A study of Mus musculus with 19 samples.

How the data were processed

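Total RNA from whole spleens of 19 mice was isolated with Trizol, labelled with biotin and hybridised to Affymetrix arrays, per the labels. The authors processed the arrays with RMA in the R package oligo, per the submitters' processing notes, whose versions are not given in the sources used here. The deposited values are log2 expression per probe set, and the 19 columns had nearly the same distribution, with values from 2.23 to 13.84 and array medians from 5.23 to 5.40. They were used as deposited, and 0 columns of the table were left unused. Each array was given its group (Aid-Cre tumour, Mb1-Cre tumour, Sca1-Cre tumour, Sca1-Cre pre-tumour or wild type) from its title.

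Of 41345 deposited probe sets, 23521 were paired with exactly 1 gene symbol, 1814 with several and 16010 with none. Of the first, 23328 were matched to the gene table by gene identifier, and 0 symbols were updated. Where several probe sets carried 1 symbol (1082 genes), the probe set with the highest mean over the 19 arrays stood for the gene, which left 22180 genes to test. No filter on dim genes was applied. Gene order for the neighbour test came from the GRCm38.p6 gene table, which placed 22126 genes.

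Groups were compared with limma 3.58.1 in R 4.3.3. One fit of group means over all 19 arrays (residual degrees of freedom 14, prior degrees of freedom 2.46) gave 9 contrasts and a moderated F-test over the 3 tumour groups; the contrast of all tumours weighted the 3 tumour groups equally. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 22180 genes, two-sided. The tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Of 40 gene lists written from general knowledge of cell types and pathways, 37 entered the tests; 1 was left out because only 2 of its genes were measured, and the driver genes and sex-linked genes were read gene by gene. Lists were tested within each comparison with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists; camera with an estimated correlation, fry and, added after camera's calls were seen, an exact two-sided permutation of the arrays on each list's mean stood beside it. Genes were named by rule: Gcsam and the driver genes, where measured, in every group; up to 10 called genes per direction for all tumours and both pre-tumour comparisons, and up to 5 for the others, among those whose groups did not overlap, leaving out predicted genes, small RNAs, receptor segments, olfactory receptors and sex-linked genes; up to 4 members of a described list with the smallest p; and the 5 genes with the smallest p, as not called, where a part had none.

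The fit was tested on simulated data with the same groups, with 50 genes changed at each size. For all tumours against wild type it recovered 44% of genes changed by 0.5 on the log2 scale, 76% at 1 and 98% at 1.5. For pre-tumour against wild type it recovered 18%, 72% and 94%. The noise was independent between genes, and more genes were changed than limma called in the real data, which loosens the threshold. The recovery in the real comparisons can thus be lower. With residuals that shared a factor across genes, camera with the preset correlation called a mean of 6.95 of 37 unchanged lists and none with an estimated correlation, and a list shifted by 1 was found in 100% and 80% of simulations.

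Alternatives were quantile normalization, cyclic loess and median centring of the deposited values; filters on dim genes that left 15245 or 12206 genes; the mean of a gene's probe sets or every probe set by itself; only the compared groups in the fit; a variance trend with robust settings; array weights per group; the replicate number as a block; a covariate for sex (Kdm5d, Uty and Eif2s3y against Xist); 1 array left out at a time; and, added after the data were seen, both arrays with pancreatic transcripts left out. Other splits of the same arrays were counted, up to 100 per comparison. The 17824 probe sets without a single symbol entered only the alternative that tested every probe set, since they name several genes or none. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were prepared with pandas 2.3.3.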

Results

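RNA from whole spleens of 19 mice was measured on Affymetrix arrays, with 1 array per animal. The mice carried a conditional human HGAL gene switched on by 1 of 3 Cre drivers, or were wild type. There were 4 Aid-Cre tumour spleens, 5 Mb1-Cre tumour spleens, 4 Sca1-Cre tumour spleens, 3 Sca1-Cre spleens taken before tumours arose (pre-tumour) and 3 wild-type spleens. HGAL is a signalling adaptor of germinal centre B cells, whose mouse counterpart is Gcsam. The Mb1-Cre and Sca1-Cre drivers carry the names of Cd79a (a chain of the B cell receptor complex, also called mb-1) and Ly6a (Sca1, a surface marker of haematopoietic stem and progenitor cells). Y-linked signal was present in 1 of 4 Aid-Cre, 4 of 5 Mb1-Cre and 2 of 4 Sca1-Cre tumour arrays, in 1 of 3 pre-tumour and in 3 of 3 wild-type arrays. Sex was thus unevenly spread over the groups. The median log2 value of an array lay between 5.23 and 5.40, and the 40th percentile between 4.72 and 4.90. A group mean below that range was taken as near background. Differences of such genes are not exact. The number of arrays limits the precision of each group. The median standard deviation over genes was 0.18 in Aid-Cre tumours, 0.17 in Mb1-Cre tumours and 0.16 in Sca1-Cre tumours, against 0.14 in wild type and 0.12 in pre-tumour spleens. The lowest correlation between arrays of 1 group was 0.929 in Aid-Cre tumours and 0.986 in wild type. Both measures depend on group size, which was 3 in wild type and pre-tumour and 4 or 5 in tumours. Part of these gaps can thus come from group size. Pancreatic transcripts were highest in 2 arrays: the exocrine pancreas list stood 2.65 above the wild-type mean in Mb1-Cre tumour replicate 2 and 0.82 above it in wild type replicate 2, while the other 2 wild-type arrays stood at -0.48 and -0.34. Pre-tumour arrays stood between -0.22 and 0.26, above the Sca1-Cre tumours at -0.55 to -0.44. All differences below are on the log2 scale, given with the standard error (SE) of limma's fit unless a standard deviation (SD) is named.

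**Figure D1:**
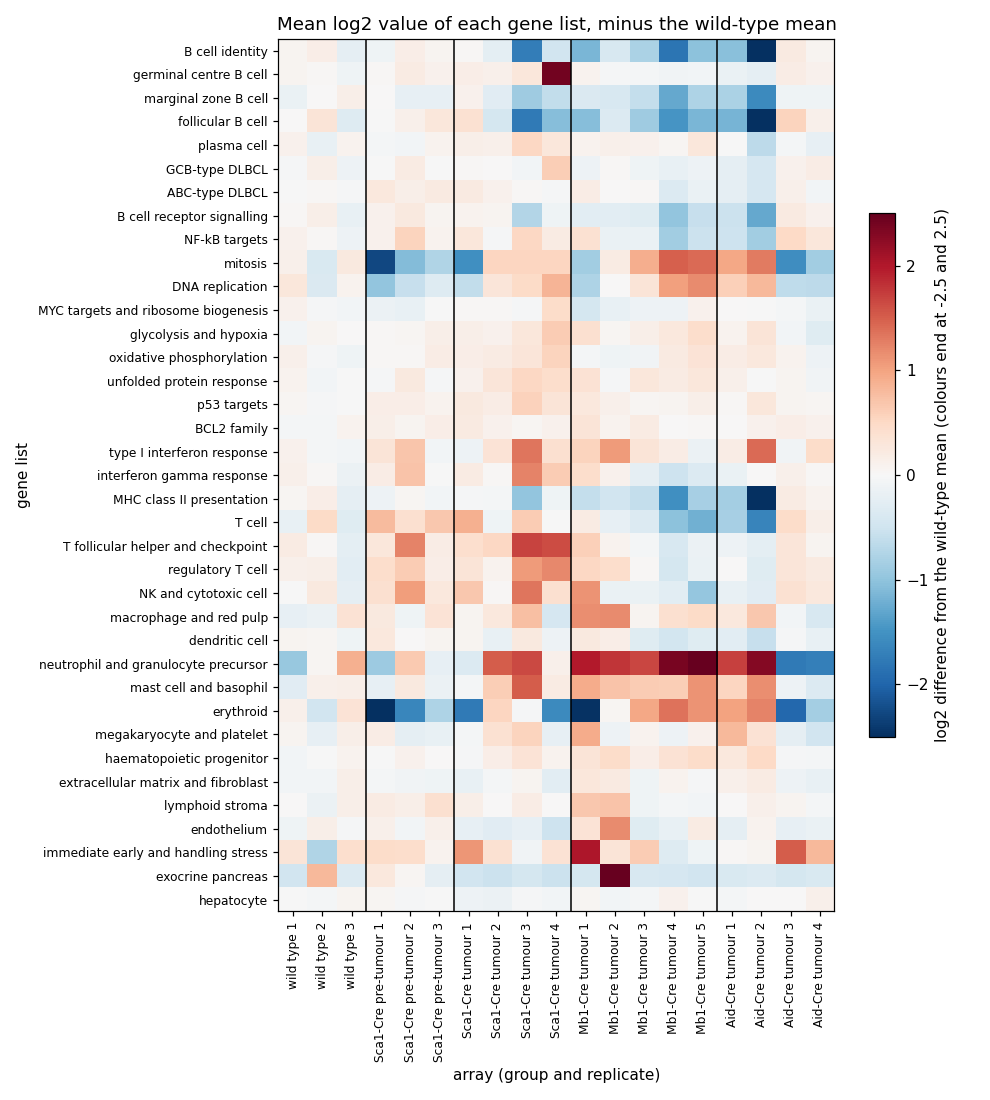
Mean log2 value of each gene list in each of the 19 arrays, minus the wild-type mean. Columns are arrays, ordered by group and replicate. The 2 arrays with the highest pancreatic signal and the germinal centre signal of Sca1-Cre tumour replicate 4 (2.41) stand out. So does the neutrophil signal of the Mb1-Cre tumours (up to 2.53), which part of the Aid-Cre (up to 2.29) and Sca1-Cre tumours (up to 1.64) also showed.

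The arrays showed no called change of the mouse Gcsam transcript in any group. Gcsam averaged 5.76 ± 0.35 (SD, n = 3) in wild type, 5.57 ± 0.40 (SD, n = 4) in Aid-Cre tumours, 5.52 ± 0.30 (SD, n = 5) in Mb1-Cre tumours and 5.83 ± 0.14 (SD, n = 3) in pre-tumour spleens. The mean of 7.09 ± 2.23 (SD, n = 4) in Sca1-Cre tumours rested on replicate 4, which reached 10.41 while the other 3 lay between 5.74 and 6.38. Its difference from wild type was 1.32 ± 0.76 (limma adjusted p = 0.545), and 0.21 without replicate 4. Whether this probe set reads the human HGAL transcript was not tested. Cd79a averaged 12.17 ± 0.19 (SD, n = 3) in wild type and 10.57 ± 0.59 (SD, n = 5) in Mb1-Cre tumours, a difference of -1.60 ± 0.63 that was not called (limma adjusted p = 0.358). Against wild type Cd79a also stood at -1.06 ± 0.66 in Aid-Cre and -0.88 ± 0.66 in Sca1-Cre tumours, and at -0.04 ± 0.70 in pre-tumour spleens, none called. Between lines it differed by 0.54 ± 0.58 (Aid-Cre minus Mb1-Cre) and -0.72 ± 0.58 (Mb1-Cre minus Sca1-Cre), not called either. Ly6a had no probe set with a single symbol and was not analysed here.

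The comparison of all 13 tumour spleens with the 3 wild-type spleens asked what the tumours of the 3 lines had in common. Prelid2, a gene of the mitochondrial lipid-transfer family PRELI, fell by 1.10 ± 0.15, or 2.14-fold (6.22 ± 0.36, SD, n = 13, against 7.29 ± 0.20, SD, n = 3). Pias3, an inhibitor of STAT3 and a SUMO ligase, fell by 0.48 ± 0.07. The small RNA genes Mir466h, at -1.66 ± 0.22, and Mir669a-3, at -2.28 ± 0.31, fell as well. These small RNA genes lie outside the naming rule and were chosen after their values were seen; they belong to a cluster of near-identical copies, so their signal cannot be given to a single copy. In each of the 4 genes every tumour array lay below every wild-type array (limma adjusted p = 0.0106 for each). No gene rose. Mgst2, a microsomal glutathione transferase, was higher by 0.99 ± 0.17 but not called (limma adjusted p = 0.0699). The next by p, also not called, were Ina (near background in both groups), Vpreb2, Zfp992 and Rab5a, with differences from 0.43 to 0.96.

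Among the gene lists, B cell identity was lower in tumours in all 20 measured members, with a mean difference of -0.86 (camera adjusted p = 1.01e-06; adjusted p = 0.735 with an estimated correlation). Its members include the B-lineage marker Ly6d at -1.72 ± 0.59, Cd79a at -1.18 ± 0.55 and the adaptor Blnk at -0.90 ± 0.48. MHC class II presentation was lower in 9 of 9 members, by -0.63 on average (camera adjusted p = 0.00359; adjusted p = 0.735 with an estimated correlation), with H2-DMb1 at -0.84 ± 0.39 and H2-Oa at -0.93 ± 0.49. Neutrophil and granulocyte precursor genes were higher in 17 of 18 members, by 0.98 (camera adjusted p = 0.00141; adjusted p = 0.735 with an estimated correlation), with the neutrophil antigen Ly6g at 1.64 ± 0.92. The type I interferon response was higher in 19 of 20 members, by 0.46 (camera adjusted p = 0.00412; adjusted p = 0.735 with an estimated correlation), with Oasl2 at 1.17 ± 0.59 and Ifit1 at 1.25 ± 0.68. The unfolded protein response was higher in 14 of 15 members, by 0.20 (camera adjusted p = 0.00332; adjusted p = 0.735 with an estimated correlation), with the chaperone Hspa5 at 0.31 ± 0.14. In these 5 lists 0 members were called by limma over all genes and 0 when adjusted over the list alone, while 3 members of B cell identity had an unadjusted p under 0.05. Immediate early genes, which also respond to handling of tissue, were higher by 0.52 in 10 of 12 members (camera adjusted p = 0.00938; adjusted p = 0.735 with an estimated correlation).

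In all, limma called 4 of 22180 genes, and 1980 genes had an unadjusted p under 0.05, where chance alone gives 1109. The count was 0 without wild type replicate 2, which carried pancreatic transcripts, 1 without wild type replicate 1 or 3, a gene that was not among the 4, 7 without Mb1-Cre tumour replicate 4 and 9 without Aid-Cre tumour replicate 4, and it was 0 with a covariate for sex, 0 with the 13 tumour arrays as 1 group and 5 with only these groups in the fit. The neutrophil and interferon shifts were not called without wild type replicates 1 and 3 respectively, where their means were 0.51 and 0.42, and immediate early genes were not called without wild type replicate 2, at 0.15.

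**Figure D2:**
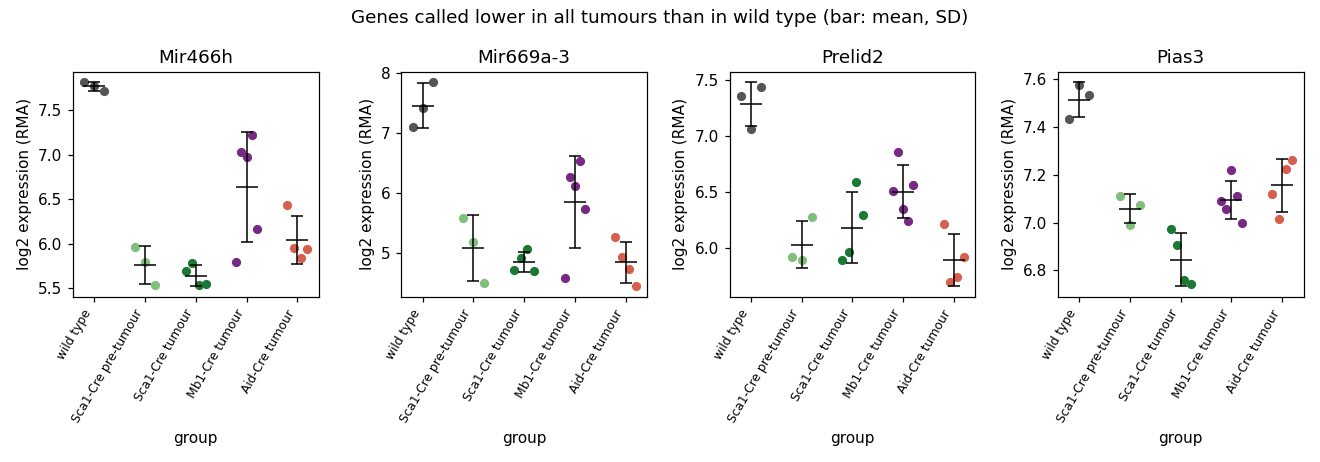
Log2 expression of Mir466h, Mir669a-3, Prelid2 and Pias3 in each array by group; points are arrays, the dash and bar are the mean and SD. Wild-type arrays lie highest for each gene, with a Prelid2 mean of 7.29 against 6.03 in pre-tumour spleens.

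Against wild type, the Aid-Cre tumours showed 1 gene that rose and 3 that fell. Vpreb2, a surrogate light chain gene of early B cells, rose by 0.73 ± 0.11 (6.43 ± 0.14, SD, n = 4, against 5.71 ± 0.13, SD, n = 3; limma adjusted p = 0.0372). Prelid2 fell by 1.40 ± 0.18 (limma adjusted p = 0.0169), and Mir466h at -1.72 and Mir669a-3 at -2.62 fell too. B cell identity genes were lower in 20 of 20 members, by -0.92 (camera adjusted p = 3.61e-06; adjusted p = 0.980 with an estimated correlation), with Ly6d at -1.50 ± 0.70 and the coactivator Pou2af1 at -0.93 ± 0.51. The spread was wide: the list mean of the 4 arrays averaged -0.92 ± 1.45 (SD), from -2.92 to 0.22, and without replicate 2 the difference was -0.25 and no longer called. MHC class II presentation was lower in 9 of 9 members, by -0.78 (camera adjusted p = 0.00202; adjusted p = 0.980 with an estimated correlation), and T cell genes in 17 of 18, by -0.47 (camera adjusted p = 0.00996; adjusted p = 0.980 with an estimated correlation), with Cd3g at -1.11 ± 0.57. Both rested on replicate 2 as well, at -0.19 and -0.08 without it, and the T cell call also ended without replicate 1 (-0.35) or wild type replicate 2 (-0.23) and stood at -0.79 without replicate 3. Immediate early genes, which also respond to handling of tissue, were called higher by camera with its preset correlation, by 0.60. That call ended without Aid-Cre tumour replicate 3 or wild type replicate 2. Plasma cell genes were lower in 13 of 16 members, by -0.22 (camera adjusted p = 0.0344; adjusted p = 0.980 with an estimated correlation), and 1 of them passed when adjusted over the list alone, the elongation factor Ell2 at -1.01 ± 0.17; the call ended without Aid-Cre tumour replicate 2 (-0.08) or 4 (-0.23) and without wild type replicate 1 or 3 (-0.18 each).

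For Aid-Cre tumours limma called 4 genes, and 1842 genes had an unadjusted p under 0.05. The count was 0 without Aid-Cre tumour replicate 2 or 3, 2 without replicate 4, of which 1 was among the 4 genes, 1 without any single wild-type array, 0 with the sex covariate and 1 with only these arrays in the fit. The gene called without wild type replicate 1 or 3, or with only these arrays, was not among the 4. In 7 runs that left out 1 array Vpreb2 was called in 0 (limma adjusted p up to 0.366), Mir466h and Mir669a-3 in 1 each, and Prelid2 in 3 (limma adjusted p up to 0.0742), with Prelid2 between -1.51 and -1.33.

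In Mb1-Cre tumours against wild type, neutrophil and granulocyte precursor genes were higher in 18 of 18 members, by 2.07 (camera adjusted p = 4.07e-10; adjusted p = 0.767 with an estimated correlation), and the list mean was 2.07 ± 0.37 (SD, n = 5) above wild type. The wild-type arrays themselves ranged from -0.94 to 0.89 on this list (SD 0.92, n = 3). Ly6g stood at 3.64 ± 1.04, the gelatinase Mmp9 at 2.33 ± 0.82, the protease Prtn3 at 2.17 ± 0.81 and the granulocyte transcription factor Cebpe at 1.11 ± 0.37. Macrophage and red pulp genes were higher in 19 of 21 members, by 0.66 (camera adjusted p = 4.51e-06; adjusted p = 0.767 with an estimated correlation), with the iron exporter Slc40a1 at 1.13 ± 0.45 and the complement gene C1qb at 1.37 ± 0.57. Mast cell and basophil genes were higher in 10 of 10 members, by 0.80 (camera adjusted p = 0.00247; adjusted p = 0.767 with an estimated correlation). B cell identity was lower in 20 of 20 members, by -1.04 (camera adjusted p = 1.39e-06; adjusted p = 0.767 with an estimated correlation), with Ly6d at -2.22 ± 0.67 and Blnk at -1.09 ± 0.55. Follicular B cell genes were lower in 7 of 7 members, by -0.98 (camera adjusted p = 0.0103; adjusted p = 0.767 with an estimated correlation), and MHC class II presentation in 9 of 9, by -0.81 (camera adjusted p = 0.00183; adjusted p = 0.767 with an estimated correlation). Mb1-Cre tumour replicate 2, 1 of the 5 arrays behind these means, carried pancreatic transcripts. Camera with its preset correlation also called immediate early genes higher, by 0.51, and T cell genes lower, by -0.52. With 1 array left out these means ran from 0.13 to 0.73 and from -0.70 to -0.28, and each call ended in some of these runs.

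No single gene passed in Mb1-Cre tumours: limma called 0 genes, with 2514 at an unadjusted p under 0.05 and a smallest adjusted p of 0.125. By smallest p in each direction, Lyz1, a lysozyme, stood at 1.06 ± 0.17 and Pias3 at -0.42 ± 0.08, while the cytidine deaminase Apobec3 stood at -2.19 ± 0.47. Zfp992, Mgst2, G0s2 and Ebi3 stood between 0.75 and 1.23, and Ccdc137, Pex10 and Ubxn11 between -1.03 and -0.37, none of them called. By list, 2 of 12 haematopoietic progenitor genes and 1 of 10 mast cell and basophil genes passed when adjusted over the list alone, and 0 neutrophil genes did. With only these 8 arrays in the fit limma called 61 genes, and without wild type replicate 3 it called 2, without wild type replicate 1, Mb1-Cre tumour replicate 3 or replicate 4 it called 1.

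In Sca1-Cre tumours against wild type, T follicular helper and checkpoint genes were higher in 13 of 14 members, by 1.07 (camera adjusted p = 2.57e-07; adjusted p = 0.411 with an estimated correlation), and 11 of them passed when adjusted over the list alone. They include the costimulator Icos at 1.48 ± 0.39, the inhibitory receptor Tigit at 2.20 ± 0.67, the adaptor Sh2d1a at 1.09 ± 0.34 and the transcription factor Tox at 1.33 ± 0.45. Regulatory T cell genes were higher in 11 of 11 members, by 0.67 (camera adjusted p = 2.54e-05; adjusted p = 0.549 with an estimated correlation), with 3 passing over the list alone. The general T cell list was higher in 15 of 18 members, by 0.35 (camera adjusted p = 0.0295; adjusted p = 0.780 with an estimated correlation). Its call ended without Sca1-Cre tumour replicate 1 (0.17) or 3 (0.26) and without wild type replicate 1 (0.26) or 3 (0.20), and it stood at 0.59 without wild type replicate 2. NK and cytotoxic cell genes were higher in 13 of 16 members, by 0.61 (camera adjusted p = 0.0110; adjusted p = 0.717 with an estimated correlation), a call that ended without Sca1-Cre tumour replicate 3 (0.37) or wild type replicate 3 (0.50). These 4 lists were also called higher in pre-tumour spleens. The interferon gamma response was higher in 17 of 18 members, by 0.52 (camera adjusted p = 2.54e-05; adjusted p = 0.549 with an estimated correlation), with Ifng itself at 1.48 ± 0.51, and by 0.28 without replicate 3. Targets of p53 were higher in 11 of 12 members, by 0.33 (camera adjusted p = 0.000102; adjusted p = 0.258 with an estimated correlation; fry adjusted p = 0.0348), and 3 passed over the list alone, with Mdm2 at 0.46 ± 0.11 and Ccng1 at 0.67 ± 0.18. Oxidative phosphorylation was higher in 15 of 17 members, by 0.30 (camera adjusted p = 1.13e-05; adjusted p = 0.549 with an estimated correlation).

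Germinal centre B cell genes were higher than in wild type in 14 of 14 members, by 0.75 (camera adjusted p = 2.80e-05; adjusted p = 0.549 with an estimated correlation), with the death receptor Fas at 1.24 ± 0.32 and S1pr2 at 1.00 ± 0.34. Without Sca1-Cre tumour replicate 4 the mean was 0.19. B cell identity was lower in 19 of 20 members, by -0.61 (camera adjusted p = 0.00709; adjusted p = 0.780 with an estimated correlation), and was not called without replicate 3, at -0.23. Among single genes Pias3 fell by 0.67 ± 0.08 (limma adjusted p = 0.00431), Prelid2 by 1.11 ± 0.18 (limma adjusted p = 0.0440), Leng8 by 0.81 ± 0.13, and the splicing factor gene U2af1l4 by 0.50 ± 0.08. Ipw, a noncoding transcript of the imprinted Prader-Willi region, was called lower (limma adjusted p = 0.0495) but lay near background in both groups, at 3.77 ± 0.09 (SD, n = 4) and 4.21 ± 0.03 (SD, n = 3), where a fall is not resolved. Outside the naming rule and chosen after their values were seen, Mir466h fell by 2.12 and Mir669a-3 fell by 2.61, while the predicted genes Gm6625 and BC064078 rose by 0.99 and 0.88. Hnrnpa0, Cwc15, Itm2c, Rab9 and Hspa13 were higher by 0.61 to 0.74 and not called.

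In all limma called 9 genes in Sca1-Cre tumours, and 2521 had an unadjusted p under 0.05. The count was 2 without Sca1-Cre tumour replicate 4 or wild type replicate 2, 3 without wild type replicate 3, 4 without wild type replicate 1, and 0 without both arrays that carried pancreatic transcripts. It was 6 with the sex covariate, 4 of them among the 9, and 2 with only these groups in the fit. Pias3 and Mir466h were called in each of 7 runs that left out 1 array, Mir669a-3 in 4, Gm6625 in 2, and Prelid2, Leng8, Ipw, U2af1l4 and BC064078 in 1 each.

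**Figure D3:**
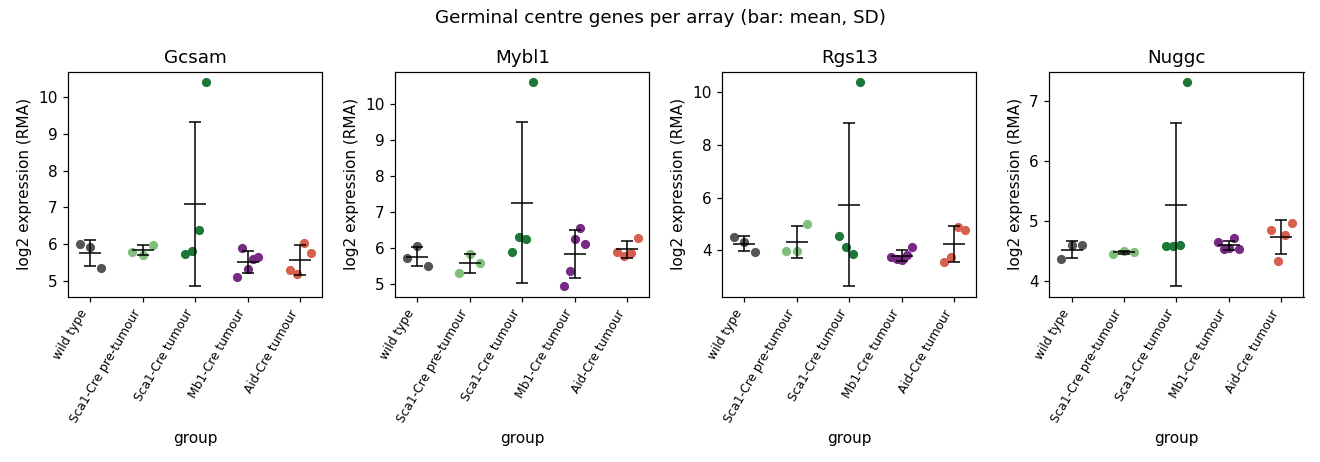
Log2 expression of Gcsam, Mybl1, Rgs13 and Nuggc in each array by group; points are arrays, the dash and bar are the mean and SD. In Sca1-Cre tumours 1 array lies far above the other 3, with Gcsam at 10.41.

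Of the genes called against wild type, 3 were shared by Aid-Cre and Sca1-Cre tumours in the same direction, Mir466h, Mir669a-3 and Prelid2. Simulated unchanged groups that shared the wild-type arrays gave a mean overlap of 0. They held independent noise, in which hardly any gene passes the threshold, so that value is no measure of what the shared wild-type arrays add. No gene was shared with Mb1-Cre tumours, where limma called 0 genes and 2514 had an unadjusted p under 0.05. The 3 wild-type arrays served each comparison and were too few to be split between them.

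The pre-tumour Sca1-Cre spleens asked what differed from wild type before tumours arose. Genes of dividing cells were lower: mitosis genes in 24 of 24 members, by -1.37 (camera adjusted p = 2.44e-11; adjusted p = 0.862 with an estimated correlation), with the proliferation marker Mki67 at -1.75 ± 0.80 and Birc5 at -2.05 ± 0.99. DNA replication genes were lower in 22 of 22 members, by -0.63 (camera adjusted p = 5.00e-05; adjusted p = 0.920 with an estimated correlation). Erythroid genes were lower in 15 of 15 members, by -1.81 (camera adjusted p = 2.09e-08; adjusted p = 0.862 with an estimated correlation), with the anion exchanger Slc4a1 at -1.58 ± 0.70 and Rhag at -2.66 ± 1.35, and by -1.20 without pre-tumour replicate 1. T cell genes were higher in 18 of 18 members, by 0.62 (camera adjusted p = 8.81e-05; adjusted p = 0.862 with an estimated correlation), with Cd4 at 1.12 ± 0.49 and the interleukin receptor Il7r at 0.98 ± 0.54. T follicular helper and checkpoint genes were higher in 13 of 14 members, by 0.57 (camera adjusted p = 0.00314; adjusted p = 0.862 with an estimated correlation), regulatory T cell genes in 11 of 11, by 0.41 (camera adjusted p = 0.00406; adjusted p = 0.862 with an estimated correlation), and NK and cytotoxic cell genes in 13 of 16, by 0.57 (camera adjusted p = 0.00314; adjusted p = 0.862 with an estimated correlation). These 3 calls ended without pre-tumour replicate 2 (0.24, 0.30 and 0.33) or wild type replicate 3 (0.45, 0.27 and 0.46). B cell identity stood at 0.04 ± 0.14 (SD, n = 3) relative to wild type. No member of these lists passed when adjusted over the list alone.

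Mir466h fell by 2.00 ± 0.28 in pre-tumour spleens (limma adjusted p = 0.0443), was chosen after its value was seen, and was the single gene called. Prelid2 at -1.26 ± 0.19 (limma adjusted p = 0.0729) and Pias3 at -0.46 ± 0.09 (limma adjusted p = 0.193) were not called. H2-Ea, an MHC class II chain gene that some inbred strains do not express, averaged 10.47 ± 0.17 (SD, n = 3) against 3.93 ± 0.27 (SD, n = 3) in wild type (near background) and was not called either (limma adjusted p = 0.193). With H2-Ea high in each pre-tumour array and near background in each wild-type and Sca1-Cre tumour array, another strain background of the pre-tumour mice was not excluded for either pre-tumour comparison. Mroh3, Vpreb2, Rab9 and Tex13b stood between 0.39 and 0.61, and Ipw, Stard4 and Pnma1 between -0.61 and -0.43, none of them called. Tex13b and Ipw were near background in both groups, Mroh3 in wild type and Pnma1 in pre-tumour spleens. With 1213 genes at an unadjusted p under 0.05, the count was 0 without any 1 of the 3 pre-tumour arrays, without wild type replicate 1 or 2, and with the sex covariate, and 3 with only these groups in the fit. It was 1 without wild type replicate 3, but Mir466h was called in 0 of 6 runs that left out 1 array, with differences from -2.10 to -1.89. An exact permutation of 3 against 3 arrays cannot give a p below 0.1, the smallest p it allows, so the list means could not pass that test.

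Within the Sca1-Cre line, tumour-bearing spleens were compared with pre-tumour spleens. Mitosis genes were higher with tumour in 24 of 24 members, by 1.39 (camera adjusted p = 4.95e-13; adjusted p = 0.522 with an estimated correlation), with the cyclin-dependent kinase Cdk1 at 1.72 ± 0.82 and Mki67 at 1.59 ± 0.75; the list stood at -1.53 in tumour replicate 1, inside the pre-tumour range of -2.27 to -0.76, and at 0.53 to 0.54 in the other 3 tumours. DNA replication genes were higher in 22 of 22 members, by 0.89 (camera adjusted p = 1.49e-11; adjusted p = 0.522 with an estimated correlation). The unfolded protein response was higher in 15 of 15 members, by 0.29 (camera adjusted p = 9.44e-06; adjusted p = 0.522 with an estimated correlation), with Sdf2l1 at 0.60 ± 0.24. Plasma cell genes were higher in 12 of 16 members, by 0.27 (camera adjusted p = 0.00154; adjusted p = 0.522 with an estimated correlation), with the disulfide isomerase Txndc5 at 0.76 ± 0.29. Erythroid genes were higher in 15 of 15 members, by 1.10 (camera adjusted p = 0.000291; adjusted p = 0.632 with an estimated correlation). These rises started from pre-tumour means below wild type, at -1.37 for mitosis, -0.63 for DNA replication and -1.81 for erythroid genes. Relative to wild type, the tumour means were 0.02 ± 1.03 for mitosis, 0.26 ± 0.62 for DNA replication and -0.71 ± 1.14 for erythroid genes (SD, n = 4). B cell identity genes were lower in 20 of 20 members, by -0.65 (camera adjusted p = 0.000559; adjusted p = 0.632 with an estimated correlation), and follicular B cell genes in 7 of 7, by -0.85 (camera adjusted p = 0.00558; adjusted p = 0.632 with an estimated correlation). Both calls ended without tumour replicate 3, at -0.28 and -0.50. Germinal centre genes were higher in 13 of 14 members, by 0.64 (camera adjusted p = 0.000131; adjusted p = 0.526 with an estimated correlation), a call that ended without tumour replicate 4, at 0.09. T follicular helper and checkpoint genes were higher in 12 of 14 members, by 0.49 (camera adjusted p = 0.00154; adjusted p = 0.570 with an estimated correlation), and this call ended without tumour replicate 3 (0.28) or pre-tumour replicate 3 (0.30), with 0.30 without tumour replicate 4 and 0.83 without pre-tumour replicate 2. Exocrine pancreas genes were lower in 12 of 12 members, by -0.53 (camera adjusted p = 0.0215; adjusted p = 0.632 with an estimated correlation). H2-Ea was near background in tumours, at 3.99 ± 0.15 (SD, n = 4) against 10.47 ± 0.17 (SD, n = 3) in pre-tumour spleens, and was not called (limma adjusted p = 0.412). Sec24d, Hspa13, Hoxa4, Oxct2a and Vaultrc5 stood between 0.30 and 0.90, and Npff, Sapcd1, Krt34 and Dnah8 between -1.96 and -0.45, none of them called, with Oxct2a near background in both groups. Limma called 0 genes, with 1185 at an unadjusted p under 0.05 and a smallest adjusted p of 0.140, and it called 1 without Sca1-Cre pre-tumour replicate 3, 1 with only these groups in the fit and 0 with the sex covariate. With 1 array left out the erythroid call ended without pre-tumour replicate 1 (0.49), and stood at 0.69 without tumour replicate 2, the plasma cell call ended without tumour replicate 3 (0.19), and the exocrine pancreas call without tumour replicate 1 (-0.54) or pre-tumour replicate 1 (-0.42).

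The tumour groups were compared with each other to ask whether tumours differed by Cre driver. Aid-Cre tumours had higher Apobec1, an RNA-editing cytidine deaminase, than Mb1-Cre tumours, by 1.32 ± 0.22 (10.29 ± 0.39, SD, n = 4, against 8.97 ± 0.39, SD, n = 5; limma adjusted p = 0.0472), and higher Klrb1c, the NK cell receptor NK1.1, by 1.31 ± 0.22, near background in Mb1-Cre tumours. They had lower Ifi202b, an interferon-inducible DNA sensor gene with near-identical copies that was near background in Aid-Cre tumours, at -2.14 ± 0.31 (limma adjusted p = 0.0312), lower Pon3 at -1.28 ± 0.22, Colec12 at -0.99 ± 0.17, Lyz1 at -0.96 ± 0.16 and the amino acid transporter Slc7a7 at -0.93 ± 0.14. The NK and cytotoxic cell list, which holds Klrb1c, was not called between these groups. Relative to wild type it averaged 0.04 ± 0.33 (SD, n = 4) in Aid-Cre and -0.08 ± 0.75 (SD, n = 5) in Mb1-Cre tumours. Outside the naming rule and chosen after their values were seen, Mir301b was higher at 0.73 and Creb3l2 and Gpsm3 were lower at -0.73 and -0.65. Neutrophil and granulocyte precursor genes were lower in 18 of 18 members, by -1.94 (camera adjusted p = 8.71e-13; adjusted p = 0.862 with an estimated correlation), 12 of them when adjusted over the list alone. Aid-Cre arrays were split, with list means of 1.71 and 2.29 above wild type in replicates 1 and 2, at the level of the Mb1-Cre arrays (1.68 to 2.53), and of -1.78 and -1.71 in replicates 3 and 4. Plasma cell genes were lower in 14 of 16 members, by -0.36 (camera adjusted p = 4.36e-06; adjusted p = 0.455 with an estimated correlation), with the secretory regulator Xbp1 at -0.69 ± 0.17, and by -0.22 without Aid-Cre tumour replicate 2. Macrophage and red pulp genes were lower in 21 of 21 members, by -0.54 (camera adjusted p = 9.77e-07; adjusted p = 0.862 with an estimated correlation), with Cd68 at -1.03 ± 0.25. Exocrine pancreas genes differed by -0.57 (camera adjusted p = 0.00541; adjusted p = 0.999 with an estimated correlation) and by 0.05 without Mb1-Cre tumour replicate 2. Limma called 10 genes, with 1942 at an unadjusted p under 0.05. The count was 0 without Aid-Cre tumour replicate 1 or 4 or Mb1-Cre tumour replicate 4 or 5, 1 without Aid-Cre tumour replicate 3, 2 without Mb1-Cre tumour replicate 2, 4 without Mb1-Cre tumour replicate 3 and 27 without Mb1-Cre tumour replicate 1. Each of the 10 genes was called in 1 to 3 of 9 runs that left out 1 array. With the sex covariate the count was 1, Ifi202b. With only these groups in the fit it was 0.

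In Aid-Cre tumours against Sca1-Cre tumours, T follicular helper and checkpoint genes were lower in 14 of 14 members, by -1.06 (camera adjusted p = 1.17e-07; adjusted p = 0.402 with an estimated correlation), 9 of them when adjusted over the list alone, with Sh2d1a at -1.24 ± 0.32 and Icos at -1.38 ± 0.36. T cell genes were lower in 18 of 18 members, by -0.82 (camera adjusted p = 2.46e-06; adjusted p = 0.537 with an estimated correlation), with Cd4 at -2.04 ± 0.43, and by -0.43 without Aid-Cre tumour replicate 2. Plasma cell genes were lower in 14 of 16 members, by -0.49 (camera adjusted p = 1.11e-05; adjusted p = 0.402 with an estimated correlation), 8 of them over the list alone, and germinal centre genes in 14 of 14, by -0.77 (camera adjusted p = 1.11e-05; adjusted p = 0.412 with an estimated correlation) or -0.22 without Sca1-Cre tumour replicate 4. Among single genes, Slc7a7 at -1.10 ± 0.14 (limma adjusted p = 0.00821), Pon3 at -1.49 ± 0.23, the inflammatory caspase Casp4 at -1.11 ± 0.17, the vesicle fusion gene Vamp7 at -1.20 ± 0.20 and Tuba1a (near background in Aid-Cre tumours) at -1.16 ± 0.19 were lower. Outside the naming rule and chosen after their values were seen, BC064078 at -1.20, Sec24d at -1.05, Hspa13 at -0.77 and Itm2c at -0.69 were lower and Mir301b was higher at 0.71. Iqsec1, Tnnc1, Leng8, Lcor and Mst1r were higher by 0.37 to 0.62 and not called. Limma called 10 genes, with 3018 at an unadjusted p under 0.05. The count was 1 without Aid-Cre tumour replicate 4 or Sca1-Cre tumour replicate 3 or 4, 3 and 4 without Aid-Cre tumour replicates 2 and 1, 43 without Sca1-Cre tumour replicate 2 and 229 without Aid-Cre tumour replicate 3. BC064078 was called in each of 8 runs that left out 1 array and the other 9 genes in 2 to 5. With the sex covariate the count was 2, BC064078 and Slc7a7, and with only these groups in the fit it was 0. The calls of Pon3, Casp4, Vamp7 and Tuba1a ended with either. With the mean of its probe sets Tuba1a stood at -0.65 and was not called.

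In Mb1-Cre tumours against Sca1-Cre tumours, neutrophil and granulocyte precursor genes were higher in 18 of 18 members, by 1.33 (camera adjusted p = 6.17e-05; adjusted p = 0.612 with an estimated correlation), and endothelium genes in 12 of 12, by 0.54 (camera adjusted p = 9.51e-05; adjusted p = 0.589 with an estimated correlation), 5 of them when adjusted over the list alone; the endothelium mean was 0.31 without Mb1-Cre tumour replicate 2, which carried pancreatic transcripts. T follicular helper and checkpoint genes were lower in 14 of 14 members, by -1.05 (camera adjusted p = 1.17e-06; adjusted p = 0.589 with an estimated correlation), 9 of them over the list alone, with Icos at -1.58 ± 0.34. T cell genes were lower in 18 of 18 members, by -0.87 (camera adjusted p = 3.48e-06; adjusted p = 0.589 with an estimated correlation), 8 of them over the list alone. The interferon gamma response was lower in 15 of 18 members, by -0.63 (camera adjusted p = 2.25e-05; adjusted p = 0.589 with an estimated correlation), with the immunoproteasome gene Psmb9 at -1.01 ± 0.24, and by -0.39 without Sca1-Cre tumour replicate 3. Exocrine pancreas genes, high in Mb1-Cre tumour replicate 2, differed by 0.69 (camera adjusted p = 0.00625; adjusted p = 0.694 with an estimated correlation) and by 0.07 without that array. Among single genes, Ifi202b at 2.27 ± 0.31 (5.65 ± 0.53, SD, n = 5, against 3.38 ± 0.14, SD, n = 4; limma adjusted p = 0.0190), Apol9a at 0.88 ± 0.11, the lipolysis inhibitor G0s2 at 0.84 ± 0.12, Rbx1-ps at 1.17 ± 0.19 and Aldh3b3 at 0.57 ± 0.09 were higher, with Ifi202b and Rbx1-ps near background in Sca1-Cre tumours, and the translation helicase Eif4a2 at -1.14 ± 0.18 and Rpp14 at -0.65 ± 0.11 were lower. BC064078 at -0.83 and Gm6644 at -0.80, chosen after their values were seen, were lower too. With the mean of its probe sets G0s2 stood at 0.46 and was not called. Limma called 9 genes, with 3893 at an unadjusted p under 0.05. The count was 0 without Sca1-Cre tumour replicate 1 or 4, 2 without Mb1-Cre tumour replicate 5, 4 without Mb1-Cre tumour replicate 3 or 4, 22 without Mb1-Cre tumour replicate 1, 44 without Sca1-Cre tumour replicate 3 and 63 without Sca1-Cre tumour replicate 2. Each of the 9 genes was called in 3 to 7 of 9 runs that left out 1 array. The count was 33 with the sex covariate, all 9 among them, and 5 with only these groups in the fit, 1 of them among the 9. Without both arrays with pancreatic transcripts each of the 9 calls ended.

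An F-test over the 3 tumour groups called 11 genes, with 3606 at an unadjusted p under 0.05. Ifi202b was high in Mb1-Cre tumours at 5.65 ± 0.53 (SD, n = 5) against 3.52 ± 0.40 (SD, n = 4) in Aid-Cre and 3.38 ± 0.14 (SD, n = 4) in Sca1-Cre tumours. Slc7a7 was low in Aid-Cre tumours at 6.98 ± 0.12 (SD, n = 4) against 7.91 ± 0.14 (SD, n = 5) and 8.08 ± 0.29 (SD, n = 4), and Pon3 shared that order. Casp4 was high in Sca1-Cre tumours at 9.16 ± 0.27 (SD, n = 4). The other 7 genes were Apol9a, BC064078, G0s2, Gpsm3, Itm2c, Mir301b and Sec24d. The naming rule does not cover this test, so its genes were chosen after their values were seen. The count was 3 without Aid-Cre tumour replicate 4 or Mb1-Cre tumour replicate 5, 5 without Aid-Cre tumour replicate 1 or Mb1-Cre tumour replicate 4, 7 without Sca1-Cre tumour replicate 4, 17 without Aid-Cre tumour replicate 2, 22 without Sca1-Cre tumour replicate 2, 30 without Mb1-Cre tumour replicate 1 and 145 without Aid-Cre tumour replicate 3. It was 5 with the sex covariate and 4 with only the tumour groups in the fit.

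Over the 9 comparisons camera called 134 list shifts with its preset correlation. With an estimated correlation 0 were called, fry called 1 in a direction, p53 targets in Sca1-Cre tumours against wild type, and exact permutation of the list means called 0 after adjustment. The smallest p that permutation allows ran from 0.00179 for all tumours to 0.1 for pre-tumour spleens against wild type. After adjustment over 37 lists no list could pass by itself at these values, so the permutation count says little. Of the 134, 48 were called in every run that left out 1 array.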

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

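Tests chosen after their result was seen were those of tumour in the spleen, sex of the animals and pancreatic RNA for the genes lower than wild type, those of strain DNA carried by each line and of DNA linked to the Cd79a locus for the differences between lines, and that of HGAL transcript read by the Gcsam probe set; the other splits, the paralogs and the normalization of the arrays were tested as written beforehand.

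The 4 genes lower in tumours than in wild type (Mir466h, Mir669a-3, Prelid2 and Pias3) had a mean difference from wild type of -1.38 ± 0.19 (mean SE). Without both arrays with the highest pancreatic signal it was -1.43 ± 0.22 (mean SE). The calls ended (Prelid2, limma adjusted p = 0.0703) with fewer wild-type arrays and a larger error. This cannot decide on pancreatic RNA in a wild-type array, as the genes were chosen with each wild-type array above each tumour array. Over the 4 genes wild type replicate 2 stood at -0.05, between replicates 1 and 3 at -0.08 and 0.13. The choice of the genes used this array too, so its place among the others decides nothing either. Against tumour in the spleen, a fit without the pre-tumour arrays called 5 genes with the 4 among them. Over the 4 genes the pre-tumour arrays (-1.52 ± 0.15, SD, n = 3) differed from the tumours of all lines (-1.35 ± 0.37, SD, n = 13) by -0.17. Beside tumours of their own line (-1.69 to -1.52) the pre-tumour arrays (-1.66 to -1.36) lay slightly higher in part. They still lay far below wild type (-0.08 to 0.13), while this cause needs them nearer to it. Even so, H2-Ea, at 10.47 against 3.99 in Sca1-Cre tumours, leaves open that the pre-tumour mice were of another strain background. Sex as the whole cause is argued against for Mir466h and Mir669a-3, as a choice without any HGAL array with Y-linked signal called both along with 3 Y-linked genes. The HGAL arrays with Y-linked signal stood at -1.67 ± 0.68 there (SD, n = 8, highest -0.73), past a stated bound of -0.98 by little more than the spread, and at 0.14 for the Y-linked genes. By the stated rule the question stays open for Prelid2 and Pias3, which that choice did not call (limma adjusted p = 0.454 and 0.494). Over these 2 genes HGAL arrays with Y-linked signal stood at -0.76 ± 0.19 (SD, n = 8), from -0.97 to -0.45. HGAL arrays without it stood at -0.82 ± 0.15 (SD, n = 8) and wild-type arrays at -0.08 to 0.08. These values go against sex as the whole cause, but both genes were chosen with these arrays. Over all 4 genes, the smaller falls among arrays with Y-linked signal were those of Mb1-Cre tumours (-1.14 to -0.70). The Mb1-Cre array without it stood at -1.51. Arrays with Y-linked signal in the other HGAL groups stood at -1.69 to -1.36, inside the range without it (-1.69 to -1.25). Line and sex thus cannot be told apart for the smaller falls. With 4 genes chosen again without the arrays compared, holding 0 to 3 of the 4, pre-tumour arrays stood at -0.84 ± 0.41 (SD of 9 pairs) and HGAL arrays with Y-linked signal at -0.63 ± 0.35 (SD of 24 pairs) from a wild-type array, and with the sex covariate the 4 calls ended (-1.31 ± 0.20, mean SE; limma adjusted p = 0.0512 to 0.0694), so a part played by sex stays open, as do, untested, the HGAL and Cre genotype and a colony or strain difference from wild type, since no HGAL mouse shares the wild-type genotype and the labels give no strain.

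Genes that differ between the tumour lines were examined for shared position, since each line could carry DNA of another strain around its Cre gene. The 100 genes that differed most between lines held 5 close pairs without a shared name stem, within the upper bound of 8 in random sets, which met the bound stated against strain DNA carried by each line; this explanation is left open, by a reading chosen after the values were seen, because the 100 genes that set each line apart held 10 such pairs for Aid-Cre and 9 for Mb1-Cre, above that bound, but 3 for Sca1-Cre. The test for paralogs was void, as 100% of the close pairs had no shared name stem and there was no excess to explain. Near Cd79a lay 1 of the genes for Mb1-Cre, the median of random sets, against a bound of 3. This argues against DNA linked to the Cd79a locus that altered many genes there, while linked DNA that altered few could not be seen. The biological difference named by the design, the Cre driver, cannot be told apart from the strain DNA of each line and stays open as untested.

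Germinal centre genes stood apart in Sca1-Cre tumour replicate 4, where the list mean was 2.41 above wild type against 0.13 to 0.28 in the other 3 arrays. The 13 germinal centre genes other than Gcsam were higher there by 2.05 ± 1.67 on average (SD over genes), 12 of them higher and 11 by at least 1, so HGAL transcript read by the Gcsam probe set does not account for the pattern. The smallest such difference over quantile normalization, cyclic loess and median centring was 2.00, which argues against the normalization of the arrays. No biological explanation was tested, as the labels give none for this array.

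Other splits of the same arrays were tested beside each count. The share of splits that called as many genes was under 0.05 for the 4 genes of all tumours against wild type (2 of 100). The real split was among these, and the highest other split called 42. It was also under 0.05 for the 9 genes of Sca1-Cre tumours against wild type (1 of 35, highest other 0). The same held for the 9 genes of Mb1-Cre against Sca1-Cre tumours (1 of 100, highest other 2). This speaks against chance there but does not exclude it. The shares were not adjusted over the comparisons, and leaving out 1 array lowered these counts to 0, 2 and 0. The share was 0.05 or more for the 4 genes of Aid-Cre tumours against wild type (2 of 35, highest other 547). So it was for the 10 of Aid-Cre against Mb1-Cre tumours (7 of 100, highest other 2617). The 10 of Aid-Cre against Sca1-Cre tumours (3 of 35, highest other 1184) and the 11 of the F-test (5 of 100, highest other 1967) were alike. For Mb1-Cre tumours against wild type (56 of 56; highest other 2) and Sca1-Cre tumours against pre-tumour spleens (35 of 35; highest other 8) limma called 0 genes, with 2514 and 1185 at an unadjusted p under 0.05; every split calls at least 0, so the splits say nothing there. For the 1 gene of pre-tumour spleens against wild type the splits are too few (1 of 10; highest other 0). Splits that called 42, 547, 1184, 1967 and 2617 genes, several times the real counts, point to a structure of the samples within the groups.

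A single array was set apart, relative to the range of its group and whatever its size, in 40 of 420 groups looked at, where chance gives about 1 in 20, or 21. Besides the germinal centre list, Sca1-Cre tumour replicate 4 stood apart in the GCB-type lymphoma list at 0.61, MYC targets at 0.46, Gcsam at 10.41, Mybl1 at 10.60, Nuggc at 7.31, Rgs13 at 10.38 and Slc40a1 at 7.23 (others 9.02 to 9.20). Sca1-Cre tumour replicate 1 stood apart in the mitosis list at -1.53 (others 0.53 to 0.54), Birc5 at 5.10, Cdk1 at 6.59, Mki67 at 9.55, Dnah8 at 6.37 and Slc7a7 at 7.65. Sca1-Cre tumour replicate 3 stood apart in MHC class II presentation at -0.99, Blnk at 8.76, H2-DMb1 at 6.78, Lcor at 8.59, Mroh3 at 4.88 and Npff at 5.28. Mb1-Cre tumour replicate 1 stood apart in the megakaryocyte list at 0.93, Apobec3 at 9.66, Ifng at 6.59, Sh2d1a at 7.33, Tox at 7.003 and Vpreb2 at 6.40. Mb1-Cre tumour replicate 2 stood apart in exocrine pancreas genes at 2.65, Dnah8 at 8.56 and Ubxn11 at 5.61, replicate 4 in Ipw at 4.02, and replicate 5 in Npff at 5.97, Oxct2a at 3.76 (others 3.80), Rab9 at 7.96 and Vamp7 at 7.19. Aid-Cre tumour replicate 1 stood apart in Krt34 at 5.89 (others 5.91), replicate 2 in p53 targets at 0.29 and Lcor at 9.65, replicate 3 in Ipw at 3.69 and Mdm2 at 8.28, and replicate 4 in Slc7a7 at 6.80.

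The change from wild type differed between tumour lines by the F-test for BC064078 (limma adjusted p = 0.00928), Ifi202b and Slc7a7 (0.0104 each), Apol9a (0.0126), G0s2, Gpsm3, Mir301b and Pon3 (0.0285 each), Casp4 (0.0333), Sec24d (0.0441) and Itm2c (0.0470). Plasma cell genes lay above the wild-type mean in every Mb1-Cre and Sca1-Cre tumour array and below it in every Aid-Cre array, though among wild-type arrays the list ranged from -0.19 to 0.10 and overlapped Mb1-Cre and Aid-Cre arrays, with differences of 0.36 and 0.49 between the lines. The opposite directions from wild type were not tested as such; camera's comparison of the lines called both differences with its preset correlation and neither with an estimated correlation. Of the probe sets without a single gene symbol, which entered only the alternative with every probe set, 16 were called higher and 16 lower than in wild type for all tumours, 17 and 5 for Aid-Cre, 2 and 1 for Mb1-Cre and 33 and 39 for Sca1-Cre tumours, and 6 and 2 for pre-tumour spleens.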

How the results depend on the processing

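The alternatives without both arrays with pancreatic transcripts and with exact permutation of list means were chosen after seeing the data. Counts of called genes depended on the processing in each comparison, and the cause was not tested except where fewer or more features, or fewer arrays, entered the fit. Counts are given in the order all tumours, Aid-Cre, Mb1-Cre, Sca1-Cre and pre-tumour against wild type, Sca1-Cre tumour against pre-tumour, Aid-Cre against Mb1-Cre, Aid-Cre against Sca1-Cre, Mb1-Cre against Sca1-Cre, and the F-test. As reported they were 4, 4, 0, 9, 1, 0, 10, 10, 9 and 11. Quantile normalization gave 5, 6, 0, 4, 1, 0, 2, 17, 5 and 7, cyclic loess 5, 5, 0, 11, 0, 0, 9, 38, 5 and 25, and median centring 6, 8, 0, 11, 2, 0, 10, 8, 3 and 15. The percentile filter gave 4, 4, 0, 6, 1, 0, 10, 12, 10 and 23, and the filter on the mean 4, 5, 0, 7, 1, 0, 8, 11, 4 and 19. The mean of probe sets gave 4, 4, 0, 14, 1, 0, 10, 9, 2 and 9, and every probe set tested by itself, which adds features, 43, 32, 3, 99, 10, 0, 7, 39, 29 and 28. Only the compared groups in the fit gave 5, 1, 61, 2, 3, 1, 0, 0, 5 and 4, the trend with robust settings 4, 3, 0, 4, 1, 0, 10, 8, 5 and 8, and array weights 17, 4, 0, 33, 21, 0, 0, 2, 8 and 3. The replicate block gave 0, 0, 2, 0, 0, 0, 0, 0, 2 and 2; of 33 pairs of arrays with 1 number 8 had a residual correlation over 0.1 (from -0.534 to 0.409), so the numbers do not pair the samples. The sex covariate gave 0, 0, 0, 6, 0, 0, 1, 2, 33 and 5. Without both arrays with pancreatic transcripts, where fewer arrays entered, the counts were 0, 1, 0, 0 and 0 against wild type, 2 for Aid-Cre and 0 for Sca1-Cre against Mb1-Cre tumours, and 7 for the F-test; with the 13 tumour arrays as 1 group the first count was 0. Counts of 0 were limma's at an adjusted p under 0.05. The overlap of calls between tumour lines was 3 with the percentile filter too.

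Leaving out 1 array at a time gave 0 to 9, 0 to 3, 0 to 2, 2 to 12, 0 to 1, 0 to 1, 0 to 27, 1 to 229, 0 to 63 and 3 to 145 genes in the same order. List shifts numbered 134 as reported, 0 with an estimated correlation, 1 with fry and 0 with exact permutation, and 118, 116, 132, 118, 129, 120 and 120 with quantile normalization, cyclic loess, median centring, the percentile filter, the block, the sex covariate and without both pancreas arrays. The direction reversed for exocrine pancreas genes in Aid-Cre against Mb1-Cre tumours, from -0.57 to 0.047 without the 2 arrays with pancreatic transcripts and likewise without Mb1-Cre tumour replicate 2 (leaving out 1 array gave list exocrine pancreas, Aid-Cre tumour vs Mb1-Cre tumour, values from -0.74 to 0.047), and for MHC class II genes in Aid-Cre against Sca1-Cre tumours, from -0.49 to 0.10 without Aid-Cre tumour replicate 2 (list MHC class II presentation, Aid-Cre tumour vs Sca1-Cre tumour, from -0.82 to 0.10). Interferon gamma genes in Sca1-Cre tumours against pre-tumour spleens (list interferon gamma response, Sca1-Cre tumour vs Sca1-Cre pre-tumour) went from 0.22 to -0.02 without Sca1-Cre tumour replicate 3. Single genes were compared under alternatives other than leaving out 1 array. Of their values 7611 stayed on the same side of the threshold, 49 passed it newly and 240 no longer passed. Among genes called as reported, 0 reversed their direction. The direction of genes not called was not compared, and genes that a filter removed gave no value. The largest shift of the median difference of all genes was 0.06, with the filter on the mean. Of 22180 genes 15245 were above the percentile filter, and changes of genes near the background were not resolved separately.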

Other observations

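Across the 13 tumour arrays erythroid and mitosis genes moved together. Their list means correlated with Pearson's r = 0.877 (permutation adjusted p = 0.00112) and Spearman's rho = 0.918 (permutation adjusted p = 0.000160), and r was 0.834 without the 2 arrays farthest from the erythroid median (in each relation, from the median of the list named first) and 0.888 within groups. Neutrophil and granulocyte precursor genes moved against B cell identity genes, with r = -0.720 (permutation adjusted p = 0.0112), rho = -0.791 (permutation adjusted p = 0.00386), r = -0.631 without the 2 farthest arrays and -0.825 within groups. Erythroid and B cell identity genes had r = -0.557 (permutation adjusted p = 0.0449) and rho = -0.571 (permutation adjusted p = 0.0588), with -0.641 without the 2 farthest arrays and -0.531 within groups. T cell and B cell identity genes had r = 0.661 (permutation adjusted p = 0.0175) and rho = 0.522 (permutation adjusted p = 0.0699), with 0.446 without the 2 farthest arrays and 0.668 within groups, so this relation rests in part on those arrays. These 4 relations were the family computed, and they were not chosen before the data were examined.

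H2-Ea was bimodal over the arrays. It averaged 10.47 ± 0.17 (SD, n = 3) in pre-tumour spleens, 3.99 ± 0.15 (SD, n = 4) in Sca1-Cre tumours, 4.06 ± 0.25 (SD, n = 4) in Aid-Cre tumours, 3.93 ± 0.27 (SD, n = 3) in wild type and 6.38 ± 3.18 (SD, n = 5) in Mb1-Cre tumours. Within Mb1-Cre tumours it was 10.79 in replicate 2 and 8.76 in replicate 4, and between 4.01 and 4.19 in the other 3 arrays. No test of strain at this locus was made.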
